A study of Mus musculus with 12 samples.

How the data were processed

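Bulk RNA was sequenced from 12 mouse libraries in 4 groups of 3. Per the labels, tumors arose after Cre recombinase, switched on by tamoxifen (3 injections) in cells that express Slc34a1, deleted Lats1 and Lats2. Primary kidney tumors and lung metastases came from such mice. Allograft tumors grew for 6 weeks after cells without Lats1 and Lats2 had been injected under the renal capsule of NOD/scid mice, which lack T and B cells. The proximal tubule libraries came from cells sorted by a red reporter from mice with Cre, conditional alleles on both copies of Lats1 and on 1 copy of Lats2. They are described as wild type, and whether their alleles had been recombined is not given in the sources used here. RNA was extracted with RNeasy Micro kits. The kind of library (poly(A) selection, ribosomal depletion), its strandedness and the date of each run are not given in the sources used here.
The deposited table held 24432 genes in FPKM (sequenced fragments scaled by transcript length and by the library's total), which the authors computed. Per the submitters' processing notes, bcl2fastq 2.17.1.14 and Salmon were used with the builds GRCm38 and mm10. The gene lengths, any filter and the version of Salmon are not given in the sources used here. The values were used as deposited. Column sums ran from 706093 to 2.5e+06 FPKM, so the values were neither TPM nor counts. Gene identifiers were matched to GENCODE M21 (24222 of 24432), and 24189 had a symbol.
Depth was not stated. It was estimated from the steps between low values, since 1 fragment adds the same FPKM to a gene of given length. In the 9 tumor libraries 95.9% of 1555 tested genes with 1 transcript took whole steps, against 45.9% of 3573 genes with several. Estimated depths were 18.5, 15.6 and 17.5 M fragments (M, mega) in primary tumors 1 to 3, 20.9, 17.4 and 16.4 in the metastases, and 18.9, 20.4 and 13.0 in the allograft tumors. In the proximal tubule libraries, which showed no exact steps, they were 5.44, 7.04 and 6.48 from low genes only. Between 2 of these libraries the commonest ratio held for 1 of 642 to 709 low genes, against 180 to 243 of 913 to 1065 in the tumors. Whether the same gene lengths and tool gave these columns is not given in the sources used here, and every fold and count against them rests on that. One fragment of a transcript of 2 kb was then worth 0.0239 to 0.0386 FPKM in tumors and 0.0710 to 0.0920 in the proximal tubule libraries, so values under 0.2 FPKM rest on a few fragments. On simulated libraries exact steps returned the set ratios and 100% of genes, and 0% after random scaling. The estimate from low genes was not simulated.
Genes at 1 FPKM or more in at least 3 of the 12 libraries were kept (16313). A pseudocount of 1 was added before log2. limma 3.58.1 in R 4.3.3 fitted the 4 groups together, with a mean-variance trend and no covariates, and tested 6 comparisons between groups. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and genes were called at an adjusted p under 0.05. limma's moderated F test counted the genes that differed among the 4 groups. Calls with 1 direction in all 3 comparisons with proximal tubule cells were counted beside 20 simulations with no effect against the same controls and beside lists drawn independently.
Fixed gene lists (34) were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 198 tests, and again with the correlation estimated from the data. Pancreatic acinar genes had fewer than 2 members past the filter and were not tested, so their values are given per library. The lists overlap: Vim, Tgfbi, Pax2, Pax8 and Ldha, among others, sit on 2 lists, and junction genes and keratins are shared by tubule, lung and tumor epithelium. The lists, the limma and camera tests and all alternatives except 2 were chosen before the data were examined.
Genes were named by a fixed rule. It takes Lats1, Lats2, Slc34a1 and the sex-linked genes, and per comparison the 6 largest called rises and the 6 largest falls with a mean of at least 10 FPKM in the higher group and no overlap, apart from predicted genes, pseudogenes and receptor segments. It also takes, per list, the 3 called members with the largest change in the main direction, 1 in the other and the most abundant member, together with 47 genes fixed as anchors. Not all of them are printed. Against a group with 0 in all libraries no fold is given.
Alternatives were pseudocounts of 0.1 and 5, no filter or 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, leaving out the 50 most abundant genes, array weights, robust variances, only the 2 groups compared, a replicate block, a 2-fold minimum and leaving out each library. After the data had been seen, 2 more were added: protein-coding genes alone with median-of-ratios scaling, and leaving out primary tumors 2 and 3. With known changes simulated for metastases against primary tumors (16313 genes, 200 changed), 33% of 2-fold and 83% of 4-fold changes were called, 0% with the wrong sign, and 0.0373% of unchanged genes. Whether these rates hold at the real spread of primary tumors was not tested. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and figures were drawn with matplotlib 3.10.9. Reads were not analysed here, so the deleted exons, isoforms and read strand were not examined.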

Results

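The 12 libraries formed 4 groups of 3: primary kidney tumors taken 4 months after tamoxifen, lung metastases, tumors grown for 6 weeks under the renal capsule of NOD/scid mice (allograft tumors), and sorted proximal tubule cells. Levels are mean ± SD FPKM of 3 libraries, and changes are log2 ± SE of FPKM + 1 with 3 libraries on each side. On this scale the change of genes with few reads is understated. Genes said to rise or fall passed limma's test at an adjusted p of 0.05, with p adjusted over all genes of a comparison. Where a gene or list was lost or gained under another setting, a lone value in brackets is its adjusted p. The adjusted p after a list's counts is that of camera over 198 tests. Counts over a list alone rest on p adjusted over that list's genes only. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.
Correlations across 16313 genes ran from 0.953 to 0.963 among the metastases and from 0.961 to 0.970 among the proximal tubule libraries. They ran from 0.919 to 0.949 among the allograft tumors and from 0.797 to 0.928 among the primary tumors, which were a spread group. The kidney genes Slc34a1, Umod and Hnf4a stood at 6.17, 209 and 9.10 FPKM in primary tumor 1. In primary tumor 2 they stood at 833, 1140.3 and 167 FPKM, and in primary tumor 3 at 166, 2278 and 54.4. The leading principal component held 62.7% of the variance. It ran from the metastases and allograft tumors over primary tumor 1 to primary tumors 3 and 2 and the proximal tubule cells.

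**Figure D1:**
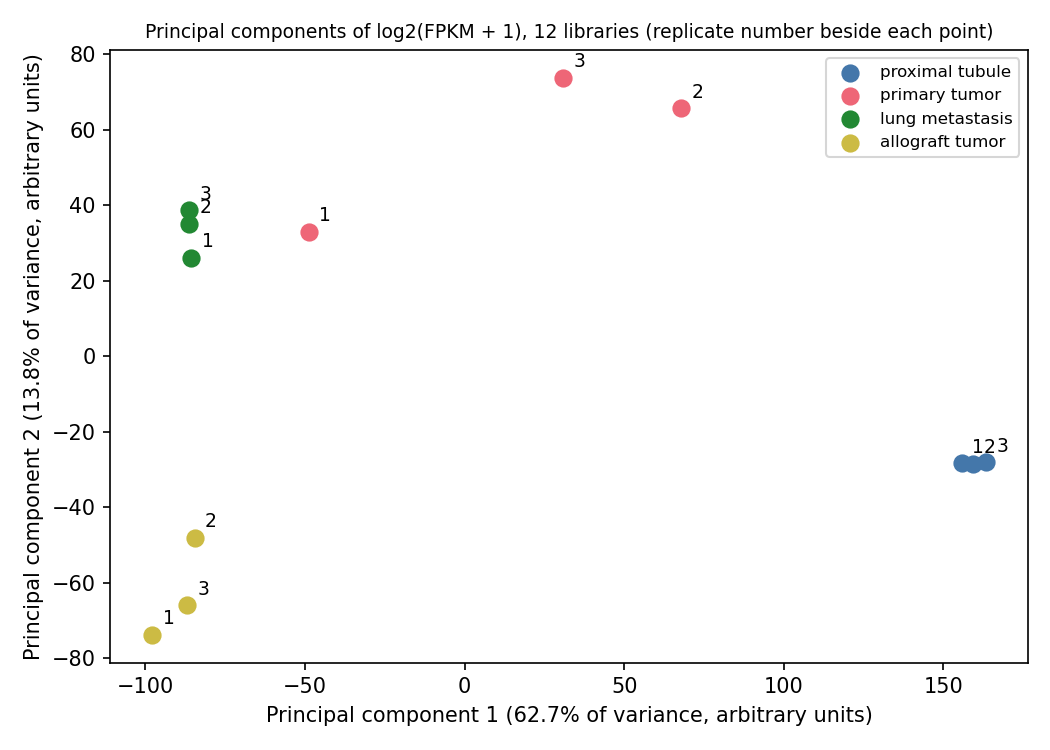
Principal components 1 and 2 of log2(FPKM + 1) in the 12 libraries, in arbitrary units, with 62.7% and 13.8% of the variance. Along component 1, primary tumors 2 and 3 lay between the proximal tubule libraries and the other tumors.

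Lats1 and Lats2 encode the kinases that restrain the coactivators YAP and TAZ, and Slc34a1 is a phosphate transporter gene of the proximal tubule. In GRCm38 coordinates, Lats1 lies at chr10:7681214-7716460, Lats2 at chr14:57689662-57758388 and Slc34a1 at chr13:55398187-55415592. Lats1 stood at 12.3, 13.0 and 14.7 FPKM in primary tumors 1 to 3, 9.54, 10.4 and 10.7 in the metastases, 5.60, 7.82 and 7.29 in the allograft tumors and 11.9, 12.7 and 12.8 in the proximal tubule cells. Lats2 stood at 19.5, 13.0 and 21.4 FPKM in the primary tumors, 22.5, 19.9 and 22.4 in the metastases, 12.2, 16.6 and 17.1 in the allograft tumors and 10.5, 10.7 and 11 in the sorted cells. Against proximal tubule cells Lats1 fell in the allograft tumors (-0.78 ± 0.15, adjusted p = 7.60e-04). Lats2 rose in primary tumors (0.66 ± 0.19, adjusted p = 0.0149, not called without primary tumor 3 (0.53, adjusted p = 0.0529)) and metastases (0.94 ± 0.19, adjusted p = 0.00141), but after TPM rescaling these changes turned to -0.37 and -0.055. Both calls were lost under all 4 other scalings, at adjusted p = 0.331 to 0.855 in primary tumors and 0.105 to 0.886 in metastases. The other 3 of these comparisons were not called. A gene-level FPKM does not resolve deleted exons, so these levels do not check the genotype, and the mice of the sorted cells carried conditional Lats alleles as well. Slc34a1 stood at 6.17, 833 and 166 FPKM in the primary tumors, 0.0169, 0.0609 and 0.0951 in the metastases, 1.37, 0.970 and 0.120 in the allograft tumors and 866, 893 and 1039.8 in the sorted cells.
Xist, expressed from the inactive X, stood at 163, 0.323 and 0.374 FPKM in the primary tumors and 94.8, 87.9 and 96.9 in the metastases. It stood at 63.7, 48.9 and 127 FPKM in the allograft tumors and 183, 156 and 141 in the proximal tubule cells. The Y-linked Ddx3y stood at 0.112, 30.0 and 20.5 FPKM in the primary tumors, 0.133, 0.259 and 0.169 in the metastases, 22.5, 22.8 and 8.94 in the allograft tumors and 0, 0 and 0 in the sorted cells. In allograft tumors against metastases, sex-linked genes gave 3 of 5 higher, 4 higher over the list alone (adjusted p = 0.0378, up, not passed without allograft tumor 2 (adjusted p = 0.0678), and adjusted p = 0.662 with an estimated correlation). The shift was also lost with a pseudocount of 5 (adjusted p = 0.0718) and after quantile normalization (0.0632). In the other 5 comparisons camera did not pass, but it did for metastases against primary tumors without primary tumor 1 (0.0105) and with array weights (0.0408), and for allograft against primary tumors without primary tumors 2 and 3 (0.00216).
Against sorted tubule cells, unsorted primary tumors held less of several tubule enzymes and receptors and more of the YAP/TAZ targets Axl, Rbms3 and Ccn2. The target list did not shift, and stroma as a source was not tested. Primary tumors 2 and 3 had a male pattern of Xist and Ddx3y and all sorted libraries a female one, so sex is confounded in part. Hpd, an enzyme gene of tyrosine breakdown, fell from 604 ± 204 to 9.82 ± 12.2 FPKM (-6.71 ± 0.86, adjusted p = 1.65e-04). The betaine enzyme gene Bhmt fell from 128 ± 13.4 to 2.61 ± 2.83 FPKM (-5.46 ± 0.43, adjusted p = 1.26e-05), as did the hormone receptor gene Prlr (-5.21 ± 0.22). The endocytic receptors Lrp2 (-2.78 ± 0.72, adjusted p = 0.00858) and Cubn (-2.94 ± 0.61, adjusted p = 0.00263) fell as well. Hnf4a, which encodes a main transcription factor of this segment, fell less (-2.28 ± 0.76, adjusted p = 0.0281, not called without proximal tubule libraries 1, 2 or 3 (-2.34 to -2.25, adjusted p = 0.0592 to 0.0684) and -1.19 without primary tumor 1), and its call was also lost when only these 2 groups were fitted (adjusted p = 0.101). The loop and collecting duct genes Cldn16 (2.28 ± 0.35) and Atp6v1g3 (2.22 ± 0.27) rose. Proximal tubule genes gave 1 of 29 higher and 13 lower, 1 higher and 12 lower over the list alone (adjusted p = 1.34e-13, down). Other nephron segment genes gave 6 of 17 higher, 5 higher over the list alone (adjusted p = 0.886, passed without primary tumor 1 at adjusted p = 4.63e-04). Podocyte genes gave 6 of 9 higher, as over the list alone (adjusted p = 0.341). The shift ended at adjusted p = 0.662 with an estimated correlation. Of these genes, 28 of 29 proximal tubule, 16 of 17 other nephron and 6 of 9 podocyte genes were higher in both primary tumors 2 and 3 than in primary tumor 1. Without primary tumors 2 and 3 the median of other nephron segment genes turned to -0.58, and with array weights the list passed (0.0465).
Axl, a receptor kinase gene, rose from 1.92 ± 0.150 to 99.9 ± 91.0 FPKM (4.75 ± 0.47, adjusted p = 4.39e-05). Rbms3 rose (4.14 ± 0.36, adjusted p = 2.25e-05), and the matricellular growth factor gene Ccn2 from 6.33 ± 1.25 to 100 ± 72.7 FPKM (3.56 ± 0.43, adjusted p = 1.24e-04). Ankrd1 rose too (2.42 ± 0.59, adjusted p = 0.00633, 1.57 without primary tumor 1, and after quantile normalization 1.31, adjusted p = 0.136), whereas Ccn1 fell from 241 ± 107 to 45.0 ± 36.8 FPKM (-2.57 ± 0.49, adjusted p = 0.00163). YAP/TAZ target genes gave 9 of 21 higher and 2 lower, as over the list alone (adjusted p = 0.822). The list median of 0.62, close to the 0.59 over all genes, turned to -0.18 after TPM rescaling and -0.02 after quantile normalization. Among Hippo components Frmd6 (2.07 ± 0.31) and Mob1a (1.62 ± 0.27) rose, and Yap1 was not called (0.56 ± 0.24, adjusted p = 0.0744), though it was when only these 2 groups were fitted (0.0183) and with array weights (0.00103). Frmd6 was not called after quantile normalization (0.97, adjusted p = 0.0501), nor Mob1a after TPM rescaling (0.56, adjusted p = 0.115). Hippo pathway components gave 10 of 18 higher and 1 lower, as over the list alone (adjusted p = 0.981). The Hippo list median of 0.59 turned to -0.42 after TPM rescaling. Wwtr1, which encodes TAZ, was called higher (0.59 ± 0.15, adjusted p = 0.00753), but its change turned to -0.48 after TPM rescaling and -0.044 after median-of-ratios scaling. It was not called after quantile normalization (0.17, adjusted p = 0.360) or without the 50 most abundant genes (0.22, adjusted p = 0.259). Of the injury genes, Lcn2 rose from 0.522 ± 0.0708 to 157 ± 154 FPKM (6.11 ± 0.88, adjusted p = 3.16e-04) and Krt19 from 0.393 ± 0.167 to 39.6 ± 22.3 (4.70 ± 0.41, adjusted p = 2.15e-05). Cp, the ceruloplasmin gene and a renal carcinoma marker, rose (4.24 ± 0.57, adjusted p = 2.12e-04). Tubule injury genes gave 9 of 16 higher, 10 higher over the list alone (adjusted p = 0.741). Renal carcinoma marker genes gave 9 of 14 higher, as over the list alone (adjusted p = 0.301). The injury list passed without primary tumors 2 and 3 (adjusted p = 0.0354), and the carcinoma markers after quantile normalization (0.0102).
Collagen and fibroblast genes rose beside markers of macrophages and lymphocytes. Col3a1 rose from 0.501 ± 0.290 to 176 ± 228 FPKM (6.01 ± 0.77, adjusted p = 1.64e-04), and the matrix proteoglycan genes Bgn (4.93 ± 0.43) and Dcn (6.00 ± 0.49) rose with it. Vim rose from 11.9 ± 1.60 to 203 ± 227 FPKM (3.40 ± 0.58, adjusted p = 8.40e-04). In the same libraries the complement gene C1qa of macrophages rose from 0.521 ± 0.159 to 174 ± 206 FPKM (6.17 ± 0.72, adjusted p = 1.00e-04), and the class II gene H2-Aa from 9.80 ± 2.08 to 600.2 ± 275 (5.73 ± 0.52, adjusted p = 2.86e-05). Cd3g and Ighm were listed at 0 in all 3 proximal tubule libraries, and at 7.25, 7.04 and 7.51 and at 71.0, 157 and 296 FPKM in primary tumors 1 to 3. The junction genes Cldn3 (3.63 ± 0.68, adjusted p = 0.00151) and Epcam (3.02 ± 0.76, adjusted p = 0.00730) rose. Extracellular matrix genes gave 18 of 22 higher, 21 higher over the list alone (adjusted p = 0.00102, up). Mesenchymal genes gave 14 of 18 higher, as over the list alone (adjusted p = 0.0178, up). Fibroblast genes gave 11 of 12 higher, as over the list alone (adjusted p = 0.00176, up). Endothelial genes gave 13 of 13 higher, as over the list alone (adjusted p = 0.0132, up). Macrophage and myeloid genes gave 14 of 14 higher, as over the list alone (adjusted p = 4.30e-04, up). T and NK cell genes gave 14 of 15 higher, as over the list alone (adjusted p = 1.11e-04, up). B and plasma cell genes gave 11 of 11 higher, as over the list alone (adjusted p = 0.00401, up). Antigen presentation genes gave 14 of 14 higher, as over the list alone (adjusted p = 1.84e-04, up). Interferon response genes gave 12 of 13 higher, as over the list alone (adjusted p = 0.0188, up). TGF-beta response genes gave 8 of 12 higher, as over the list alone (adjusted p = 0.221). Epithelial junction genes gave 16 of 24 higher, as over the list alone (adjusted p = 0.426). The 9 passing shifts ended at adjusted p = 0.662 to 0.70 with an estimated correlation. Without primary tumors 2 and 3 the Epcam change was 2.81, and the endothelial and B cell medians were lower (1.54 and 1.21). The TGF-beta list passed after TPM rescaling (0.0279) and after quantile normalization (0.0328), as did the junction list after the last (0.00963). The interferon shift was lost when only these 2 groups were fitted (0.0564).
Immediate early genes, which also respond to tissue dissociation, were high in the sorted cells. Fosb stood at 139 ± 71.7 FPKM there and 0.682 ± 0.461 in primary tumors (-6.28 ± 0.73, adjusted p = 9.70e-05), and Fos at 268 ± 122 and 8.82 ± 4.04 (-4.77 ± 0.66, adjusted p = 2.57e-04). Immediate early and dissociation genes gave 10 of 15 lower, as over the list alone (adjusted p = 1.34e-13, down). This shift was lost at adjusted p = 0.609 with an estimated correlation. Pkm, the pyruvate kinase gene, rose from 22.4 ± 5.13 to 171 ± 49.1 FPKM (2.86 ± 0.30, adjusted p = 6.29e-05). Acsl1, which activates fatty acids, fell (-2.28 ± 0.64, adjusted p = 0.0132). The replication gene Mcm3 (1.96 ± 0.44, adjusted p = 0.00401), the cell cycle inhibitor gene Cdkn2b (1.97 ± 0.33, adjusted p = 7.81e-04) and Pfkfb3 (1.80 ± 0.34) rose, and Ndrg1 fell (-2.41 ± 0.61). After quantile normalization Mcm3 (0.85, adjusted p = 0.185), Cdkn2b (0.75, adjusted p = 0.0950) and Pfkfb3 (0.90, adjusted p = 0.0768) were not called, nor was Pfkfb3 after TPM rescaling (0.109). Glycolysis genes gave 6 of 17 higher, as over the list alone (adjusted p = 0.712). Fatty acid oxidation genes gave 3 of 22 lower, no calls over the list alone (adjusted p = 2.15e-08, down). Oxidative phosphorylation genes gave no calls among 21, as over the list alone (adjusted p = 8.64e-07, down). Gluconeogenesis genes gave 1 of 7 higher, no calls over the list alone (adjusted p = 0.00117, down). In the last 3 lists primary tumor 2 averaged 7.03, 8.78 and 8.49, above all sorted libraries (at most 6.65, 8.15 and 8.00). Cell cycle genes gave 13 of 27 higher, as over the list alone (adjusted p = 0.378). Hypoxia response genes gave 4 of 16 higher and 1 lower, as over the list alone (adjusted p = 0.217). The p53 target and cell cycle arrest genes gave 7 of 13 higher, as over the list alone (adjusted p = 0.741). None of the 3 passing shifts was kept, at adjusted p = 0.662 with an estimated correlation. The gluconeogenesis shift was also lost after TPM rescaling (0.0893) and quantile normalization (0.104). The cell cycle list passed after TPM rescaling (0.00750) and after median-of-ratios scaling (0.0374). After TPM rescaling the medians of the glycolysis (0.46), hypoxia (0.39) and p53 (0.69) lists turned to -0.57, -0.62 and -0.28. The glycolysis median was also -0.15 after median-of-ratios scaling, where hypoxia was -0.19, and after quantile normalization hypoxia was -0.46 and p53 -0.06.
The largest rises were in small RNA genes. Mir6236, which overlaps ribosomal sequence, stood at 486118 ± 5453 FPKM against 31.4 ± 29.0 (15.19 ± 1.4, adjusted p = 2.93e-05). Mir3473f was listed at 0 in all proximal tubule libraries and at 686, 471 and 725 FPKM in the primary tumors. Over all genes, 7861 were called higher and 800 lower of 16313 (8661 together, 90.8% higher), around a median shift of 0.59 toward the primary tumors. The share of higher calls was 58.6% after median-of-ratios scaling, 35.9% after TPM rescaling, 39.4% after quantile normalization and 75.0% without the 50 most abundant genes. In 10156 genes (62.3%, against 10% by chance) the 3 libraries of each group did not overlap.

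**Figure D2:**
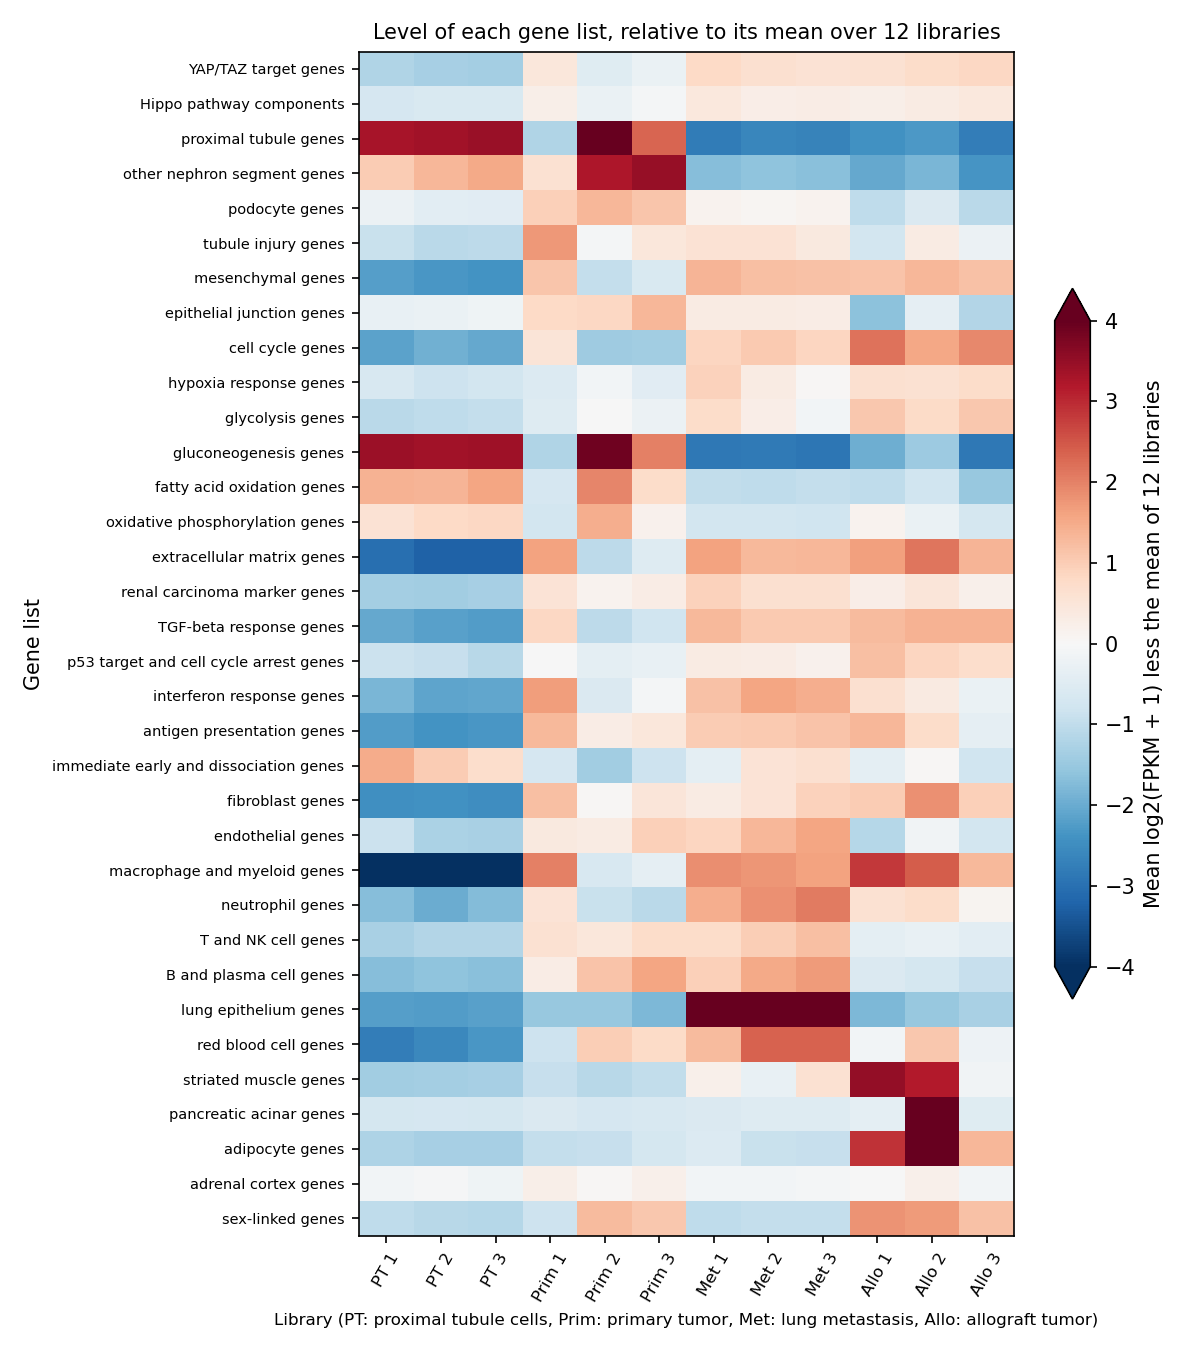
Mean log2(FPKM + 1) of each gene list in the 12 libraries, less the mean of that list over all libraries (color scale in log2 units, ending at 4 on either side). Before that subtraction, proximal tubule genes averaged 3.03, 8.58 and 6.56 in primary tumors 1 to 3 and 1.46 to 1.63 in the metastases.

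Lung metastases had lost nearly all expression of proximal tubule genes and held high Vim, Axl and Krt19. Miox, an inositol-degrading enzyme gene, fell from 2391 ± 213 to 0.0440 ± 0.0386 FPKM (-11.16 ± 1.38, adjusted p = 6.02e-05). Slc34a1 (-9.78 ± 1.27), Cubn (-7.41 ± 0.61) and Hnf4a (-7.62 ± 0.76) fell with them. The renal lineage factor gene Pax8 fell less, from 39.1 ± 4.55 to 18.3 ± 6.21 FPKM (-1.1 ± 0.30, adjusted p = 0.00845). Hao2 was listed at 0 in all metastases and at 882, 1330.1 and 997 FPKM in the sorted cells. Umod fell (-7.74 ± 0.76). Proximal tubule genes gave 26 of 29 lower, as over the list alone (adjusted p = 1.61e-18, down). Other nephron segment genes gave 2 of 17 higher and 14 lower, as over the list alone (adjusted p = 2.52e-08, down). Podocyte genes gave 2 of 9 higher and 2 lower, as over the list alone (adjusted p = 0.453). Neither shift was kept, at adjusted p = 0.662 with an estimated correlation. The podocyte median of 0.55 turned to -0.03 after median-of-ratios scaling and -0.30 after TPM rescaling.
Axl rose from 1.92 ± 0.150 to 186 ± 23.2 FPKM (5.99 ± 0.47, adjusted p = 4.42e-06) and Ankrd1 from 0.757 ± 0.720 to 50.6 ± 2.40 (4.95 ± 0.59, adjusted p = 4.86e-05). Ccn2 (3.89 ± 0.43) and the matrix gene Ccdc80 (5.77 ± 0.80) rose, Nuak2 fell (-1.81 ± 0.23) and Ccn1 was not called (-0.55 ± 0.49, adjusted p = 0.338), but was lower after TPM rescaling (-1.61, adjusted p = 0.0176). Tead2, which encodes a DNA-binding partner of YAP, rose from 0.312 ± 0.0788 to 15 ± 1.84 FPKM (3.61 ± 0.49, adjusted p = 1.04e-04), and Wwtr1 rose (1.18 ± 0.15, adjusted p = 6.63e-05, not called after TPM rescaling at 0.15, adjusted p = 0.563). Krt19 rose from 0.393 ± 0.167 to 144 ± 9.21 FPKM (6.71 ± 0.41, adjusted p = 1.11e-06), as did Lcn2 (7.73 ± 0.88, adjusted p = 3.57e-05), while the injury gene Prom1 fell (-2.65 ± 0.54, adjusted p = 0.00132). Lgals3 rose (4.65 ± 0.21) and Amacr fell (-3.50 ± 0.88) among renal carcinoma markers. YAP/TAZ target genes gave 16 of 21 higher and 1 lower, 17 higher and 1 lower over the list alone (adjusted p = 0.140). Hippo pathway components gave 10 of 18 higher and 1 lower, as over the list alone (adjusted p = 0.598). Tubule injury genes gave 7 of 16 higher and 3 lower, as over the list alone (adjusted p = 0.875). Renal carcinoma marker genes gave 8 of 14 higher and 3 lower, as over the list alone (adjusted p = 0.490). The injury list median of 0.83 turned to -0.06 after quantile normalization, where the YAP/TAZ list passed (0.0190).
Vim, the intermediate filament gene of mesenchymal cells, rose from 11.9 ± 1.60 to 992 ± 53.6 FPKM (6.27 ± 0.58, adjusted p = 1.09e-05), as did Cdh2 (3.67 ± 0.71, adjusted p = 0.00101). The collagen gene Col6a1 (6.71 ± 0.42) and Postn (7.65 ± 1.18) rose with them. The same libraries held lung transcripts. Scgb1a1, a club cell gene, and Sftpc, a surfactant gene, were listed at 0 in all proximal tubule libraries and at 6438, 9267 and 11197 and at 3851, 5344 and 5694 FPKM in the metastases. Mesenchymal genes gave 18 of 18 higher, as over the list alone (adjusted p = 0.00147, up). Extracellular matrix genes gave 21 of 22 higher, as over the list alone (adjusted p = 2.60e-04, up). TGF-beta response genes gave 10 of 12 higher, 11 higher over the list alone (adjusted p = 0.0213, up). Fibroblast genes gave 11 of 12 higher, as over the list alone (adjusted p = 0.00929, up). Lung epithelium genes gave 15 of 15 higher, as over the list alone (adjusted p = 6.58e-09, up). All 5 passing shifts were lost at adjusted p = 0.609 to 0.672 with an estimated correlation. Epithelial genes were split, with Krt18 (3.85 ± 0.29) and Cdh1 (1.65 ± 0.45, adjusted p = 0.00779) up and Cldn2 (-3.50 ± 0.65) and Cdh16 (-3.37 ± 0.63) down. Cdh1 was not called after TPM rescaling (0.62, adjusted p = 0.284) or median-of-ratios scaling (1.07, adjusted p = 0.0585). Epithelial junction genes gave 12 of 24 higher and 4 lower, 13 higher and 4 lower over the list alone (adjusted p = 0.712). Its median was positive (1.12) while camera placed it below the other genes.
Top2a, which unwinds DNA in dividing cells, rose from 1.26 ± 0.354 to 55.3 ± 4.97 FPKM (4.65 ± 0.65, adjusted p = 1.28e-04), as did Mki67 (3.66 ± 0.54, adjusted p = 1.72e-04). Pkm rose from 22.4 ± 5.13 to 476 ± 146 FPKM (4.33 ± 0.30, adjusted p = 2.32e-06), and the hexokinase gene Hk2 (3.93 ± 0.52) and lactate exporter gene Slc16a3 (4.82 ± 0.43) rose too. Of the genes for making glucose, G6pc (-8.18 ± 1.31) and Pck1 (-10.40 ± 1.59) fell. The peroxisomal gene Ehhadh (-5.42 ± 1.02, adjusted p = 8.42e-04), its regulator Ppara (-4.74 ± 0.63, adjusted p = 9.40e-05) and the complex II gene Sdha (-1.92 ± 0.46, adjusted p = 0.00372) fell. Ankrd37, a hypoxia target, rose (3.71 ± 0.30), as did the p53 target Phlda3 (2.90 ± 0.37). Cell cycle genes gave 26 of 27 higher, as over the list alone (adjusted p = 6.23e-04, up). Glycolysis genes gave 9 of 17 higher and 1 lower, as over the list alone (adjusted p = 0.590). Gluconeogenesis genes gave 1 of 7 higher and 6 lower, as over the list alone (adjusted p = 1.93e-04, down). Fatty acid oxidation genes gave 21 of 22 lower, as over the list alone (adjusted p = 1.21e-11, down). Oxidative phosphorylation genes gave 19 of 21 lower, 20 lower over the list alone (adjusted p = 1.67e-09, down). Hypoxia response genes gave 10 of 16 higher and 1 lower, as over the list alone (adjusted p = 0.468). The p53 target and cell cycle arrest genes gave 11 of 13 higher and 1 lower, as over the list alone (adjusted p = 0.184). None of the 4 passing shifts was kept, at adjusted p = 0.662 to 0.687 with an estimated correlation.
Immune, vessel and blood genes rose beside the lung markers. Lyz2, which shares reads with Lyz1, rose from 0.920 ± 0.400 to 4178 ± 438 FPKM (11.10 ± 0.62, adjusted p = 6.08e-07), as did the neutrophil gene S100a8 (6.55 ± 0.75, adjusted p = 3.90e-05). The endothelial gene Egfl7 (4.09 ± 0.34), the hemoglobin gene Hbb-bs (6.96 ± 0.72) and the heart muscle gene Myh6 (6.01 ± 0.33) rose. Egr1, an immediate early gene, stood at 6.91 ± 1.78 FPKM against 70.7 ± 24.1 in the sorted cells (-3.14 ± 0.33, adjusted p = 2.27e-05). Macrophage and myeloid genes gave 14 of 14 higher, as over the list alone (adjusted p = 8.92e-04, up). Neutrophil genes gave 8 of 8 higher, as over the list alone (adjusted p = 0.0136, up). T and NK cell genes gave 15 of 15 higher, as over the list alone (adjusted p = 2.36e-04, up). B and plasma cell genes gave 11 of 11 higher, as over the list alone (adjusted p = 0.00556, up). Endothelial genes gave 13 of 13 higher, as over the list alone (adjusted p = 0.00899, up). Antigen presentation genes gave 14 of 14 higher, as over the list alone (adjusted p = 9.04e-04, up). Interferon response genes gave 13 of 13 higher, as over the list alone (adjusted p = 0.00654, up). Immediate early and dissociation genes gave 2 of 15 higher and 5 lower, as over the list alone (adjusted p = 0.00343, down). Red blood cell genes gave 4 of 4 higher, as over the list alone (adjusted p = 0.0574, passed without lung metastases 1, 2 or 3 or proximal tubule 3 at adjusted p = 0.0276 to 0.0489). Striated muscle genes gave 5 of 8 higher, as over the list alone (adjusted p = 0.378). Adrenal cortex genes gave 1 of 2 higher and 1 lower, as over the list alone (adjusted p = 0.581). The 8 passing shifts ended at adjusted p = 0.662 to 0.684 with an estimated correlation. The immediate early shift was also lost after quantile normalization (0.177), and the red blood cell list passed under all 4 other scalings (adjusted p = 0.00596 to 0.0192), as did muscle genes after TPM rescaling (0.0162).
Over all genes, 8803 were called higher and 2355 lower in metastases (11158 together, 78.9% higher) around a median shift of 0.68. The share of higher calls was 58.3% after median-of-ratios scaling, 43.7% after TPM rescaling, 46.5% after quantile normalization and 63.8% without the 50 most abundant genes. In 13614 genes (83.5%, against 10% by chance) the groups did not overlap.
Allograft tumors, unsorted as well, also held little of most tubule genes, with the highest mean Ankrd1, Col3a1 and Top2a of the 4 groups and low Cdh1. Miox fell from 2391 ± 213 to 0.404 ± 0.459 FPKM (-10.78 ± 1.38, adjusted p = 6.37e-05), as did the glutathione transferase gene Gsta2 (-9.40 ± 0.89). Slc34a1 (-9.07 ± 1.27), Hnf4a (-7.21 ± 0.76), Pax8 (-1.68 ± 0.30) and the thick limb gene Slc12a1 (-5.90 ± 0.86) fell too. Of the podocyte genes, Npnt fell (-3.02 ± 0.48) and Ptpro rose (2.38 ± 0.36). Proximal tubule genes gave 27 of 29 lower, as over the list alone (adjusted p = 3.70e-16, down). Other nephron segment genes gave 16 of 17 lower, as over the list alone (adjusted p = 6.39e-10, down). Podocyte genes gave 3 of 9 higher and 4 lower, 3 higher and 5 lower over the list alone (adjusted p = 0.0412, down, not passed without proximal tubule 1 or allograft tumors 1 or 3 at adjusted p = 0.0530 to 0.0712). All 3 passing shifts were lost at adjusted p = 0.662 with an estimated correlation. The podocyte shift was lost in 9 of the other settings too, among them all 4 other scalings (adjusted p = 0.109 to 0.357).
Ankrd1 rose from 0.757 ± 0.720 to 399.5 ± 91.6 FPKM (7.88 ± 0.59, adjusted p = 4.40e-06), Axl to 312 ± 78.3 (6.71 ± 0.47, adjusted p = 3.14e-06) and Ccn2 to 244 ± 97.6 (5.01 ± 0.43, adjusted p = 7.94e-06). Ccn1 was not called (0.18 ± 0.49, adjusted p = 0.766). Tead2 rose from 0.312 ± 0.0788 to 48.4 ± 13.0 FPKM (5.21 ± 0.49, adjusted p = 1.13e-05), and Wwc1, which encodes a LATS activator, fell (-2.18 ± 0.28, adjusted p = 5.84e-05). Wwtr1 was called higher (0.60 ± 0.15, adjusted p = 0.00447), but its change turned to -0.76 after TPM rescaling, -0.025 after median-of-ratios scaling and -0.091 without the 50 most abundant genes, and it was not called after quantile normalization (0.10, adjusted p = 0.536). Krt19 rose (5.98 ± 0.41), Itgb6 fell (-4.60 ± 0.27) and the carcinoma marker Tgfbi rose (6.23 ± 0.54). YAP/TAZ target genes gave 13 of 21 higher and 2 lower, as over the list alone (adjusted p = 0.217). Hippo pathway components gave 10 of 18 higher and 3 lower, 11 higher and 3 lower over the list alone (adjusted p = 0.741). Tubule injury genes gave 8 of 16 higher and 3 lower, 8 higher and 4 lower over the list alone (adjusted p = 0.581). Renal carcinoma marker genes gave 9 of 14 higher and 3 lower, as over the list alone (adjusted p = 0.688). The Hippo list median of 0.69 turned to -0.60 after TPM rescaling.
Cdh1, the epithelial cadherin gene, fell from 15.4 ± 1.84 to 3.61 ± 3.73 FPKM (-2.13 ± 0.45, adjusted p = 0.00166), as did Cdh16 (-6.36 ± 0.63, adjusted p = 1.47e-05). The keratin genes Krt8 (1.77 ± 0.23, adjusted p = 7.70e-05) and Krt18 (5.12 ± 0.29, adjusted p = 1.14e-06) and the mesenchymal cadherin gene Cdh2 (4.91 ± 0.71, adjusted p = 1.39e-04) rose, though Krt8 was not called after TPM rescaling (0.35, adjusted p = 0.326). Vim rose to 694 ± 94.9 FPKM (5.75 ± 0.58, adjusted p = 1.59e-05) and Postn from 0.0228 ± 0.0394 to 723 ± 308 (9.37 ± 1.18, adjusted p = 5.80e-05), with Col3a1 (8.92 ± 0.77) up as well. Markers of fat and muscle rose in the same libraries. Cfd and Adipoq, made by adipocytes, were listed at 0 in the proximal tubule libraries and at 401, 1557 and 63.8 and at 79.5, 218 and 13.7 FPKM in allograft tumors 1 to 3. Acta1, the skeletal muscle actin gene, stood at 267, 227 and 1.00 FPKM against 0, 0.333 and 0. Pancreatic digestive enzyme genes stood out in allograft tumor 2 alone: Ctrb1 at 0.499, 799 and 0.121 FPKM and Prss2 at 0.184, 606 and 0.267 in allograft tumors 1 to 3 (both named after their values were seen), and the 8 genes of that list averaged 7.15 on the log2 scale there and at most 0.30 in each other library. Epithelial junction genes gave 7 of 24 higher and 11 lower, as over the list alone (adjusted p = 0.00104, down). Mesenchymal genes gave 18 of 18 higher, as over the list alone (adjusted p = 0.00133, up). Extracellular matrix genes gave 18 of 22 higher, as over the list alone (adjusted p = 4.50e-04, up). TGF-beta response genes gave 11 of 12 higher, as over the list alone (adjusted p = 0.0110, up). Fibroblast genes gave 10 of 12 higher, as over the list alone (adjusted p = 0.00602, up). Adipocyte genes gave 6 of 6 higher, as over the list alone (adjusted p = 0.0616). Striated muscle genes gave 6 of 8 higher, as over the list alone (adjusted p = 0.254). None of the 5 passing shifts was kept, at adjusted p = 0.662 to 0.672 with an estimated correlation. The junction shift was also lost after TPM rescaling (0.0574), and the adipocyte list passed under all 4 other scalings (adjusted p = 9.10e-04 to 0.0116). Muscle genes passed after TPM rescaling (0.00292), after quantile normalization (0.0449) and without the 50 most abundant genes (0.0355).
Top2a rose from 1.26 ± 0.354 to 176 ± 90.7 FPKM (6.19 ± 0.65, adjusted p = 1.98e-05), as did Cdk1 (5.13 ± 0.66) and the replication clamp gene Pcna (3.15 ± 0.32). Cdkn2a, which encodes cell cycle inhibitors, was listed at 0 in all proximal tubule libraries and at 50.9, 24.2 and 54.1 FPKM in the allograft tumors. Its neighbor Cdkn2b rose (4.22 ± 0.33, adjusted p = 5.16e-06). Pkm rose from 22.4 ± 5.13 to 737 ± 180.2 FPKM (4.97 ± 0.30, adjusted p = 1.75e-06), and Hk2 (4.84 ± 0.52), Ldha (1.65 ± 0.38) and the collagen hydroxylase gene P4ha1 (2.5 ± 0.34) rose with it, but Ldha was not called after TPM rescaling (0.23, adjusted p = 0.539). Fbp1 (-7.72 ± 1.11), Acaa1b (-7.14 ± 0.92) and Sdha (-2.43 ± 0.46) fell. Cell cycle genes gave 27 of 27 higher, as over the list alone (adjusted p = 1.01e-05, up). The p53 target and cell cycle arrest genes gave 11 of 13 higher, as over the list alone (adjusted p = 0.0352, up). Glycolysis genes gave 13 of 17 higher, as over the list alone (adjusted p = 0.0442, up, not passed without proximal tubule 1 or allograft tumors 1 or 3 at adjusted p = 0.0567 to 0.0701). Hypoxia response genes gave 12 of 16 higher and 1 lower, as over the list alone (adjusted p = 0.214). Gluconeogenesis genes gave 1 of 7 higher and 6 lower, as over the list alone (adjusted p = 9.82e-04, down). Fatty acid oxidation genes gave 19 of 22 lower, 20 lower over the list alone (adjusted p = 2.54e-10, down). Oxidative phosphorylation genes gave 9 of 21 lower, 1 lower over the list alone (adjusted p = 1.12e-05, down). The 6 passing shifts ended at adjusted p = 0.662 to 0.672 with an estimated correlation. The p53 shift was lost in 4 of the other settings (adjusted p = 0.0513 to 0.0574) and the glycolysis shift in 3 (adjusted p = 0.0508 to 0.0748), while hypoxia genes passed after quantile normalization (0.0470).
C1qa rose from 0.521 ± 0.159 to 1009.7 ± 655 FPKM (9.15 ± 0.72, adjusted p = 5.24e-06), and Mmp9 (7.01 ± 0.52) and the T helper gene Cd4 (2.5 ± 0.20) rose beside it. The T cell gene Cd3e (0.04 ± 0.22, adjusted p = 0.870) and the B cell gene Cd79a (-0.10 ± 0.42, adjusted p = 0.836) were not called in these tumors of immunodeficient hosts. The heat shock gene Hspa1a fell (-3.40 ± 0.55, adjusted p = 2.98e-04). Macrophage and myeloid genes gave 14 of 14 higher, as over the list alone (adjusted p = 3.81e-04, up). Neutrophil genes gave 8 of 8 higher, as over the list alone (adjusted p = 0.141). T and NK cell genes gave 9 of 15 higher, 7 higher over the list alone (adjusted p = 0.334). B and plasma cell genes gave 3 of 11 higher, as over the list alone (adjusted p = 0.988). Endothelial genes gave 3 of 13 higher, as over the list alone (adjusted p = 0.636). Antigen presentation genes gave 14 of 14 higher, as over the list alone (adjusted p = 0.00522, up). Interferon response genes gave 11 of 13 higher, as over the list alone (adjusted p = 0.109). Immediate early and dissociation genes gave 2 of 15 higher and 10 lower, as over the list alone (adjusted p = 1.11e-04, down). All 3 passing shifts were lost at adjusted p = 0.662 to 0.684 with an estimated correlation. Interferon (adjusted p = 0.0127 to 0.0470) and neutrophil genes (adjusted p = 0.00801 to 0.0449) passed under all 4 other scalings, and T and NK cell genes after TPM rescaling (0.00895). The endothelial median of 0.18 turned negative under all 4 other scalings (-0.37 after median-of-ratios scaling), and the B cell median of 0.44 turned to -0.33 after quantile normalization.
Over all genes, 8521 were called higher and 2755 lower in allograft tumors (11276 together, 75.6% higher) around a median shift of 0.66. The share of higher calls was 57.1% after median-of-ratios scaling, 33.6% after TPM rescaling, 50% after quantile normalization and 54.6% without the 50 most abundant genes. In 12335 genes (75.6%, against 10% by chance) the groups did not overlap.
Across the 4 groups 12968 genes differed by limma's F test. In all 3 tumor groups 5984 genes were called higher and 670 lower than in proximal tubule cells (6654 together). The risers included Axl, Ccn2, Ankrd1, Krt18, Krt19, Vim, Col3a1, Pkm and C1qa, and the fallers Hpd, Bhmt, Cubn, Hnf4a, Fosb and Fos. The share of higher calls among shared genes was 57.0% after median-of-ratios scaling, 30.5% after TPM rescaling, 39.7% after quantile normalization and 69.6% without the 50 most abundant genes. The 3 comparisons share the same 3 control libraries. Lists of these sizes drawn independently would share 2216 higher and 19.5 lower genes. At an unadjusted p under 0.05, 7390 genes changed 1 way in all 3 comparisons, against a mean of 77.8 in 20 simulations with no effect against the same controls. Lacking tumor effects, these simulations do not size the part due to common controls.

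**Figure D3:**
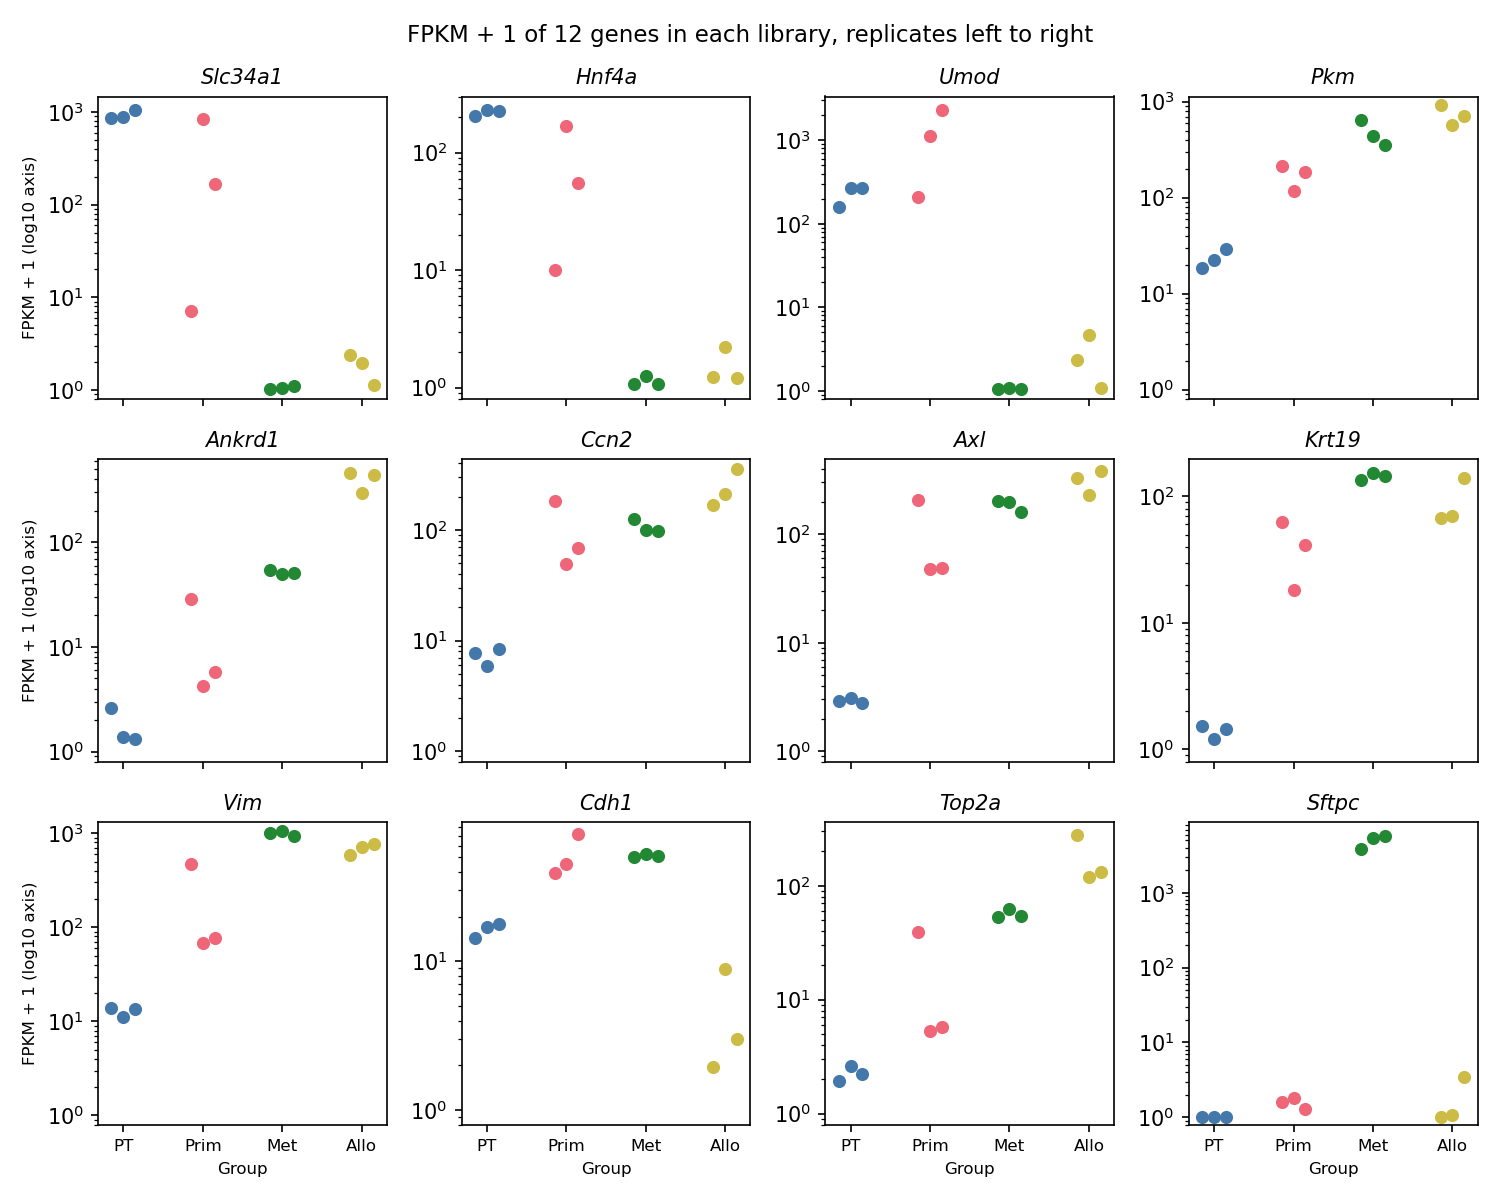
FPKM + 1 of 12 genes in every library, on a log10 axis. Ankrd1 averaged 0.757 FPKM in proximal tubule cells and 12, 50.6 and 399.5 in primary tumors, metastases and allograft tumors.

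Metastases differed from primary tumors most in lung genes and in the kidney genes present in the primary tumors. Sftpb and Scgb3a2, both made in lung, stood at 879.9 ± 102 and 518 ± 119 FPKM against 0.158 ± 0.160 and 0.0624 ± 0.108 (Sftpb 9.57 ± 0.18, adjusted p = 5.62e-10). Umod stood at 0.0557 ± 0.0167 against 1209 ± 1036 FPKM (-9.60 ± 0.76, adjusted p = 1.84e-05). The fatty acid carrier gene Slc27a2 (-7.85 ± 0.91), Hnf4a (-5.34 ± 0.76, adjusted p = 9.91e-04) and the collecting duct junction gene Cldn8 (-4.54 ± 0.33) fell. Lung epithelium genes gave 15 of 15 higher, as over the list alone (adjusted p = 8.21e-27, up). Proximal tubule genes gave 23 of 29 lower, 27 lower over the list alone (adjusted p = 2.00e-12, down). Other nephron segment genes gave 13 of 17 lower, 14 lower over the list alone (adjusted p = 9.92e-11, down). Podocyte genes gave 1 of 9 higher and 4 lower, 1 higher and 5 lower over the list alone (adjusted p = 0.0183, down, not passed without primary tumors 1, 2 or 3 at adjusted p = 0.0699 to 0.179). None of the 4 passing shifts was kept, at adjusted p = 0.118 to 0.662 with an estimated correlation. The podocyte shift was also lost with the filter at 5 FPKM (0.250) and with array weights (0.0539).
Vim rose from 203 ± 227 to 992 ± 53.6 FPKM (2.88 ± 0.58, adjusted p = 0.00726), and Col6a1 (2.50 ± 0.42, adjusted p = 0.00261) and Krt19 (2.01 ± 0.41, adjusted p = 0.00780) rose, in libraries that also held lung epithelium. Among YAP/TAZ targets Tgfb2 rose (1.94 ± 0.39, adjusted p = 0.00752), while Axl (1.25 ± 0.47, adjusted p = 0.0849) and Ccn2 (0.33 ± 0.43, adjusted p = 0.628) were not called. Ankrd1 rose (2.5 ± 0.59, adjusted p = 0.0150, not called without primary tumors 2 or 3 or lung metastases 1, 2 or 3 (2.00 to 2.56, adjusted p = 0.0516 to 0.0651)). Ccn1 rose (2.03 ± 0.49, adjusted p = 0.0177, not called without primary tumors 2 or 3 or lung metastases 1, 2 or 3 (1.63 to 2.05, adjusted p = 0.0559 to 0.0720)). Top2a rose (2.40 ± 0.65, adjusted p = 0.0281, not called without primary tumors 2 or 3 or lung metastases 1, 2 or 3 (1.89 to 2.44, adjusted p = 0.0754 to 0.108)). Slc16a3 (3.52 ± 0.43) and Ankrd37 (2.95 ± 0.30) rose, and the mitochondrial regulator gene Ppargc1a fell (-2.73 ± 0.43, adjusted p = 0.00192). YAP/TAZ target genes gave 5 of 21 higher, 7 higher and 1 lower over the list alone (adjusted p = 0.0130, up, not passed without primary tumor 2 or lung metastasis 1 at adjusted p = 0.0551 to 0.0700). Mesenchymal genes gave 10 of 18 higher, 13 higher over the list alone (adjusted p = 2.48e-04, up). Extracellular matrix genes gave 8 of 22 higher and 1 lower, 16 higher and 1 lower over the list alone (adjusted p = 4.01e-04, up). TGF-beta response genes gave 5 of 12 higher, 7 higher over the list alone (adjusted p = 0.00109, up). Cell cycle genes gave 25 of 27 higher, 26 higher over the list alone (adjusted p = 2.76e-09, up). Hypoxia response genes gave 5 of 16 higher and 1 lower, as over the list alone (adjusted p = 0.00529, up, not passed without primary tumor 1 at adjusted p = 0.0591). Fatty acid oxidation genes gave 8 of 22 lower, 17 lower over the list alone (adjusted p = 1.04e-06, down). Oxidative phosphorylation genes gave no calls among 21, as over the list alone (adjusted p = 6.85e-05, down). The 8 passing shifts ended at adjusted p = 0.662 to 0.672 with an estimated correlation. Many of these results rested on primary tumors 2 and 3, whose male pattern of Xist and Ddx3y no metastasis shared, confounding sex. Without primary tumors 2 and 3, Ankrd1, Ccn1, Top2a, Krt19 and Tgfb2 changed less, by 0.83, 0.80, 0.51, 1.21 and 0.77. The list medians were 0.19 (mesenchymal), 0.35 (TGF-beta), 0.093 (YAP/TAZ), -0.0047 (oxidative phosphorylation) and 0.077 (matrix, 1.58 with all 3). When only these 2 groups were fitted, Vim (0.0777), Col6a1 (0.0505), Krt19 (0.0556), Tgfb2 (0.0750), Ankrd1 (0.0905), Ccn1 (0.0772) and Top2a (0.119) were not called. Axl and Ccn2 were called with array weights (2.65e-05 and 0.0402) and without primary tumor 1 (1.94, adjusted p = 8.33e-05, and 0.88, adjusted p = 0.0454). Array weights ended the hypoxia shift (0.0551).
Neutrophil genes were higher in the metastases beside the lung genes. Retnlg stood at 29.6 ± 11.2 against 2.45 ± 2.15 FPKM (3.23 ± 0.40, adjusted p = 4.00e-04), and S100a8 (4.52 ± 0.75), the endothelial cadherin gene Cdh5 (2.15 ± 0.32) and Myh6 (6.15 ± 0.33) rose. Neutrophil genes gave 7 of 8 higher, as over the list alone (adjusted p = 5.39e-05, up). Macrophage and myeloid genes gave 2 of 14 higher, as over the list alone (adjusted p = 0.00657, up, not passed without primary tumor 2 at adjusted p = 0.0761). Endothelial genes gave 6 of 13 higher and 1 lower, as over the list alone (adjusted p = 0.0375, up, not passed without primary tumors 1 or 2 or lung metastasis 3 at adjusted p = 0.0741 to 0.175). Immediate early and dissociation genes gave 7 of 15 higher, 10 higher over the list alone (adjusted p = 2.48e-04, up). Red blood cell genes gave 2 of 4 higher, 4 higher over the list alone (adjusted p = 0.0271, up, not passed without primary tumor 1 at adjusted p = 0.149). Striated muscle genes gave 3 of 8 higher, 5 higher over the list alone (adjusted p = 0.00995, up, not passed without primary tumor 1 at adjusted p = 0.0553). T and NK cell genes gave 4 of 15 higher, 7 higher and 1 lower over the list alone (adjusted p = 0.0776, passed without primary tumor 3 or lung metastasis 1 at adjusted p = 0.0218 to 0.0314). All 6 passing shifts were lost at adjusted p = 0.662 to 0.707 with an estimated correlation. The endothelial shift was also lost after TPM rescaling (0.0543) and with array weights (0.355), which ended those of red blood cell (0.0754) and muscle genes (0.226) too, while T and NK cell genes passed after TPM rescaling (0.0438). Without primary tumors 2 and 3 the macrophage median turned to -0.46 and the S100a8 change was 2.67. Over all genes, 1849 were called higher and 1565 lower (3414 together, 54.2% higher, and 43.0% without the 50 most abundant genes). The count was unstable: 6215 without primary tumor 1, 1924 and 1679 without primary tumor 2 or 3, and 1519, 1162 and 1280 without metastasis 1, 2 or 3. It was 1178 when only these 2 groups were fitted. In 6855 genes (42.0%, against 10% by chance) the groups did not overlap.
Allograft tumors differed from primary tumors by higher Cdkn2a, Ankrd1 and cell cycle genes and by lower junction, vessel, kidney and lymphocyte genes. Cdkn2a stood at 43.1 ± 16.4 against 1.1 ± 0.199 FPKM (4.32 ± 0.27, adjusted p = 1.31e-05), and Ankrd1 at 399.5 ± 91.6 against 12 ± 13.8 (5.46 ± 0.59, adjusted p = 1.64e-04). Ccn1 (2.75 ± 0.49, adjusted p = 0.00177) and Axl (1.97 ± 0.47, adjusted p = 0.00785) rose, while the target Nt5e (-1.50 ± 0.31, adjusted p = 0.00393) and Yap1 itself (-0.97 ± 0.24, adjusted p = 0.00998) fell. Msln, the mesothelin gene, rose from 1.39 ± 1.22 to 173 ± 119 FPKM (6.11 ± 0.46, adjusted p = 3.51e-05). Top2a (3.94 ± 0.65, adjusted p = 0.00120), Hk2 (3.03 ± 0.52), Cdh2 (3.71 ± 0.71) and the matrix gene Fbln2 (4.70 ± 0.61) rose. Cdh1 fell from 51.3 ± 17.3 to 3.61 ± 3.73 FPKM (-3.76 ± 0.45, adjusted p = 2.76e-04), as did Cdh16 (-6.49 ± 0.63). YAP/TAZ target genes gave 7 of 21 higher and 2 lower, 7 higher and 3 lower over the list alone (adjusted p = 0.110, passed without primary tumor 1 or allograft tumor 1 at adjusted p = 0.0186 to 0.0376). Cell cycle genes gave 27 of 27 higher, as over the list alone (adjusted p = 3.31e-12, up). The p53 target and cell cycle arrest genes gave 8 of 13 higher and 1 lower, 9 higher and 1 lower over the list alone (adjusted p = 0.00189, up). Glycolysis genes gave 9 of 17 higher, as over the list alone (adjusted p = 3.99e-04, up). Hypoxia response genes gave 9 of 16 higher and 1 lower, as over the list alone (adjusted p = 0.00324, up). Mesenchymal genes gave 11 of 18 higher, 13 higher over the list alone (adjusted p = 0.00236, up). Extracellular matrix genes gave 13 of 22 higher and 1 lower, 14 higher and 1 lower over the list alone (adjusted p = 0.00180, up). TGF-beta response genes gave 9 of 12 higher, as over the list alone (adjusted p = 0.00116, up). Epithelial junction genes gave 3 of 24 higher and 16 lower, as over the list alone (adjusted p = 6.85e-05, down). None of the 8 passing shifts was kept, at adjusted p = 0.662 to 0.687 with an estimated correlation. Without primary tumors 2 and 3, the mesenchymal, matrix and TGF-beta medians were 0.07, 0.16 and 0.36. Axl, Yap1 and Nt5e changed by 0.57, -0.89 and -0.80 there. Axl (0.0695) and Yap1 (0.0899) were not called when only these 2 groups were fitted.
Fat and muscle genes rose in the same libraries, with Cfd at 401, 1557 and 63.8 against 0, 0.190 and 0.253 FPKM (8.23 ± 0.89, adjusted p = 1.62e-04), and Adipoq (5.86 ± 0.73) and Myh6 (4.45 ± 0.33) up. Kidney genes were lower, with Umod (-8.50 ± 0.76) and Hnf4a (-4.93 ± 0.76) down. The T cell gene Cd3g (-2.77 ± 0.22), the plasma cell gene Jchain (-5.57 ± 0.42) and the vessel gene Emcn (-2.07 ± 0.25) fell. Adipocyte genes gave 6 of 6 higher, as over the list alone (adjusted p = 5.56e-04, up). Striated muscle genes gave 5 of 8 higher, as over the list alone (adjusted p = 0.020, up, not passed without primary tumor 1 at adjusted p = 0.0565). Proximal tubule genes gave 26 of 29 lower, 27 lower over the list alone (adjusted p = 1.76e-08, down). Other nephron segment genes gave 16 of 17 lower, as over the list alone (adjusted p = 5.76e-10, down). Podocyte genes gave 7 of 9 lower, as over the list alone (adjusted p = 1.90e-04, down). T and NK cell genes gave 9 of 15 lower, as over the list alone (adjusted p = 2.15e-04, down). B and plasma cell genes gave 10 of 11 lower, as over the list alone (adjusted p = 5.56e-04, down). Endothelial genes gave 8 of 13 lower, 9 lower over the list alone (adjusted p = 0.00111, down). Macrophage and myeloid genes gave 8 of 14 higher, 11 higher over the list alone (adjusted p = 0.00159, up). The 9 passing shifts ended at adjusted p = 0.609 to 0.672 with an estimated correlation. The macrophage median was 0.073 without primary tumors 2 and 3. Over all genes, 3345 were called higher and 3439 lower (6784 together, 49.3% higher, but 31.9% after TPM rescaling and 29.3% without the 50 most abundant genes). The count was 2916 when only these 2 groups were fitted. In 7130 genes (43.7%, against 10% by chance) the groups did not overlap.

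**Figure D4:**
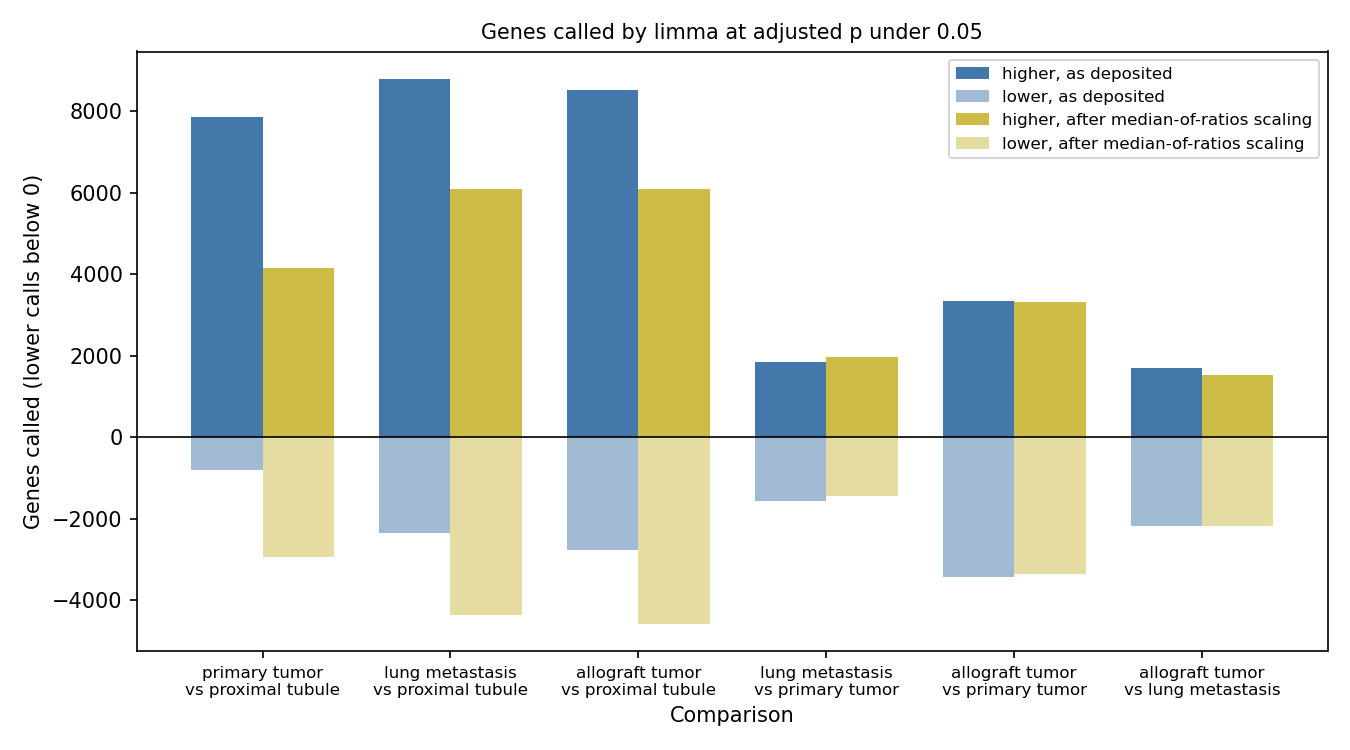
Genes called higher (above 0) and lower (below 0) in each comparison, as deposited and after median-of-ratios scaling. As deposited, primary tumors had 7861 higher calls against proximal tubule cells.

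Between allograft tumors and metastases 2 of 29 tubule genes and 4 of 21 YAP/TAZ targets were called. Junction, vessel and lymphocyte genes and markers of the site differed. Cdh1 fell from 50.3 ± 1.06 to 3.61 ± 3.73 FPKM (-3.78 ± 0.45, adjusted p = 2.39e-04), while Krt8 rose (1.20 ± 0.23, adjusted p = 0.00454, not called after TPM rescaling at 0.84, adjusted p = 0.0850). Cdkn2a rose from 1.13 ± 0.285 to 43.1 ± 16.4 FPKM (4.30 ± 0.27, adjusted p = 3.20e-06), and the replication gene Mcm7 (1.81 ± 0.29), Eno2 (1.61 ± 0.15) and Ankrd1 (2.93 ± 0.59, adjusted p = 0.00543) rose. The receptor kinase gene Kit fell (-3.39 ± 0.34, adjusted p = 8.33e-05) and Vim was not called (-0.52 ± 0.58, adjusted p = 0.568), but it was without primary tumors 2 and 3 (0.0304). Proximal tubule genes gave 1 of 29 higher and 1 lower, 1 lower over the list alone (adjusted p = 0.835). YAP/TAZ target genes gave 1 of 21 higher and 3 lower, as over the list alone (adjusted p = 0.845). Epithelial junction genes gave 3 of 24 higher and 14 lower, 3 higher and 15 lower over the list alone (adjusted p = 4.21e-05, down). Cell cycle genes gave 5 of 27 higher, as over the list alone (adjusted p = 8.46e-05, up). Glycolysis genes gave 5 of 17 higher, 6 higher over the list alone (adjusted p = 0.00534, up). The p53 target and cell cycle arrest genes gave 2 of 13 higher, as over the list alone (adjusted p = 0.0375, up, not passed without lung metastasis 3 or allograft tumor 1 at adjusted p = 0.0619 to 0.0744). All 4 passing shifts were lost at adjusted p = 0.662 to 0.672 with an estimated correlation. Quantile normalization also ended the glycolysis (0.0632) and p53 shifts (0.0721), and 3 further settings the p53 shift (adjusted p = 0.0521 to 0.0581).
Markers of the surrounding tissue differed, with Sftpc at 0.863 ± 1.42 against 4963 ± 979 FPKM (-11.61 ± 0.40, adjusted p = 3.04e-08) and Adipoq at 104 ± 104 against 0.230 ± 0.349 (5.73 ± 0.73, adjusted p = 3.47e-04). The vessel gene Esam (-2.69 ± 0.36), the T cell gene Cd2 (-2.84 ± 0.24), the B cell gene Ms4a1 (-2.71 ± 0.30) and the interferon target Rsad2 (-1.57 ± 0.26) fell. The fibroblast genes Lum (3.05 ± 0.48) and Dcn (2.72 ± 0.49) rose. Lung epithelium genes gave 14 of 15 lower, as over the list alone (adjusted p = 6.33e-23, down). Adipocyte genes gave 6 of 6 higher, as over the list alone (adjusted p = 5.81e-05, up). Endothelial genes gave 12 of 13 lower, 13 lower over the list alone (adjusted p = 1.93e-08, down). T and NK cell genes gave 13 of 15 lower, as over the list alone (adjusted p = 2.15e-08, down). B and plasma cell genes gave 9 of 11 lower, 10 lower over the list alone (adjusted p = 8.39e-07, down). Neutrophil genes gave 1 of 8 higher and 4 lower, as over the list alone (adjusted p = 0.0338, down, not passed without allograft tumor 3 at adjusted p = 0.0601). Interferon response genes gave 4 of 13 lower, as over the list alone (adjusted p = 0.00443, down). None of the 7 passing shifts was kept, at adjusted p = 0.118 to 0.672 with an estimated correlation. The neutrophil shift was also lost in 3 of the other settings (adjusted p = 0.0504 to 0.0707). Over all genes, 1703 were called higher and 2169 lower (3872 together, 44.0% higher). The share of higher calls was 17.5% after TPM rescaling, 54.8% after quantile normalization and 23.9% without the 50 most abundant genes. The count fell to 2432, 2032 and 1944 without metastasis 1, 2 or 3. In 7904 genes (48.5%, against 10% by chance) the groups did not overlap.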

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

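As stated, 2 alternatives were added after the results were seen. With 3 libraries per group, the comparisons with proximal tubule cells were the steadiest in number when 1 library was left out. Their share of higher calls moved with every scaling. Leaving out 1 library gave 7046 to 9116 calls in primary tumors, 9813 to 10350 in metastases and 10335 to 10948 in allograft tumors against proximal tubule cells, 11833 to 13310 genes by the F test and 5329 to 7370 shared genes. It gave 1162 to 6215 calls for metastases against primary tumors, 4905 to 7947 for allograft tumors against primary tumors, 1944 to 3653 for allograft tumors against metastases, and 98 to 106 passing list tests. Among fits without 1 library, the highest count of metastases against primary tumors came without primary tumor 1, which left the 2 primary tumors with kidney transcripts. Quantile normalization left 5738 calls in primary tumors against proximal tubule cells and 3878 shared genes. A 2-fold minimum, which can only lower a count, left 5083 and 3639 of these, 4231 for allograft against primary tumors and 2270 for allograft tumors against metastases. Array weights gave 9743 calls for metastases against primary tumors and 6511 for allograft tumors against metastases. Fitting only the 2 groups compared gave 1178 calls for metastases and 2916 for allograft tumors against primary tumors. The same setting gave 7357, 13108 and 11237 calls for primary tumors, metastases and allograft tumors against proximal tubule cells and 4187 for allograft tumors against metastases. Without primary tumors 2 and 3 these counts were 1096 and 3188, where the lone primary tumor is assumed to vary like the other groups. Where construction does not show it, the cause was not tested.
Of 198 list tests 102 passed with the preset correlation and 0 with an estimated one (98 to 112 under the other settings), so the list results rest on the preset. Without primary tumors 2 and 3, which leaves 1 library in that group, some list results passed no more and others passed anew or turned. Gene calls were lost and gained as well. Mesenchymal and TGF-beta genes passed no more in metastases or allograft tumors against primary tumors, nor did YAP/TAZ targets in metastases. Camera's direction turned in 5 lists: other nephron segment genes in primary tumors against proximal tubule cells (median -0.58), extracellular matrix (0.077, where the median only shrank), interferon (-0.23) and macrophage genes (-0.46) in metastases against primary tumors, and oxidative phosphorylation genes in allograft against primary tumors (0.47). Wwtr1 in primary tumors against proximal tubule cells turned to -0.48 after rescaling to TPM, -0.044 after median-of-ratios scaling and -0.013 with protein-coding genes. In allograft tumors it turned to -0.76, -0.025 and -0.0095, and to -0.091 without the 50 most abundant genes. Lats2 turned to -0.37 in primary tumors and -0.055 in metastases after rescaling to TPM. The cause was not tested. Of 186 named gene results, 157 kept their direction and their side of the threshold under all planned settings, and 29 did not, 7 of them with a replicate left out. Of 198 list results 139 did so and 59 did not, apart from the estimated correlation. The filter at 5 FPKM gave no value for Cd3e, and the 50 most abundant genes include Mir6236.
The replicate block gave 8536, 11050 and 11133 calls for primary tumors, metastases and allograft tumors against proximal tubule cells, 3334 and 6547 for metastases and allograft tumors against primary tumors and 3639 for allograft tumors against metastases. It moved no count by more than 1.5 times. Residuals of libraries with the same number correlated from -0.04 to 0.10, and 5 of 12 libraries correlated best with their own number, so the data give no hint that the numbers pair libraries. The proximal tubule libraries had an estimated 5.44 to 7.04 M fragments and 15574 to 15696 genes above 0, against 19291 to 21070 genes in the tumor libraries. Whether depth, the sorted cell type or the library kind limits this number was not tested.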

Other observations

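Histone genes, whose main transcripts lack poly(A) tails, had a median of 132, 19.9 and 18.9 FPKM in primary tumors 1 to 3, 174, 202 and 182 in the metastases and 614, 301 and 454 in the allograft tumors, against 5.60, 3.88 and 3.25 in the proximal tubule libraries. Members of this cluster share reads. Mitochondrial genes summed to 22114 FPKM in primary tumor 1, 213076 in primary tumor 2 and 119272 in primary tumor 3. In the proximal tubule libraries they summed to 210637, 225721 and 181707. All 27 cell cycle, 22 extracellular matrix, 18 mesenchymal and 14 macrophage genes were lower in both primary tumors 2 and 3 than in primary tumor 1, while 28 of 29 proximal tubule genes were higher in both.
Tests of the library kind, of normal kidney tissue, of the male sex pattern and of depth on genes chosen by 2 groups were chosen only after the result was seen.
Most calls against proximal tubule cells were higher in the tumors as deposited, but 35.9%, 43.7% and 33.6% were after rescaling to TPM, so this pattern rests on the scaling. Lower depth of the proximal tubule libraries stays open. It predicted at most 60 percent higher calls among 5044 genes with a mean of 20 FPKM or more, where the lowest comparison had 71.8%, but 9 of the 12 libraries averaged were tumors, which favors risers. With genes chosen by both groups alike the lowest was 67.7%, under the 70 percent set against depth. Another kind of RNA library for the proximal tubule samples, such as selection for poly(A) tails, may contribute, since the median of 115 snoRNA and scaRNA genes lay 2.75 log2 units or more above that of all genes in each comparison. The sorting of cells and a real rise in the tumors stay open, because the library kind and the tissue are confounded with the group. Other gene lengths or another tool for the proximal tubule columns stay open too, untested. Cells of stroma, blood and host tissue in unsorted pieces stay open as well and were not tested as a cause of this pattern.
Primary tumors 2 and 3 held far more proximal tubule transcripts than primary tumor 1. Normal kidney tissue in the pieces taken is a candidate explanation, since 22 of 26 genes of other nephron segments and podocytes (84.6%) were higher in both, with Umod at 1140.3 and 2278 FPKM against 209. The male sex pattern of primary tumors 2 and 3 as the whole cause is argued against, since 27 of 29 proximal tubule genes (93.1%) were at least 2-fold higher, and beyond 2 SD, in the proximal tubule group, with a female pattern as well, than in primary tumor 1. Kap and Slc7a13 were the exceptions, for which the sex pattern stays open. As a part of the cause it cannot be told apart from normal tissue, because 13 of 29 genes (44.8%) had a mean in the proximal tubule group above both, and the other 16 did not. A tumor that kept its differentiation stays open for the proximal tubule genes, and no test separated it from normal tissue.
Allograft tumors held Xist and Y-linked transcripts together. As shares of libraries with 1 pattern alone, these added up to 1.13, 1.02 and 1.25 in allograft tumors 1 to 3, near the 1 that a mixture needs, so cells of both sexes, those of the graft and of the host, may lie in 1 piece. The sex of donors and hosts is not given in the sources used here. Which transcripts came from the host was not tested.
With 10 ways to split 6 libraries, the splits are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. Against proximal tubule cells the real split gave 8661, 11158 and 11276 calls and the highest other split 3, 1 and 1. Metastases against primary tumors gave 3414 and at most 6, allograft tumors against metastases 3872 and 5, and allograft against primary tumors 6784 and 441. For the F test (12968 genes, highest other 9612) and the shared genes (6654, highest other 5184), 1 of 100 splits of the 12 libraries was as large, the real one, which excludes chance only if libraries are independent. For the list tests 6 of 100 splits passed as many as the real 102 (highest other 108), so chance is not excluded.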
